A study of Mus musculus with 6 samples.

How the data were processed

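Total RNA from hippocampal CA1 tissue of C57BL/6 mice at P14 was measured in 6 libraries, 3 from mice given N-bc2S1P and 3 from mice given saline. Per the labels' protocols, about 25 mg of tissue was extracted with TRIzol, samples with an RNA integrity number of at least 8 were used, and libraries were made with a directional kit after removal of ribosomal RNA, with fragmentation at 94 C for 8 min and 13 PCR cycles. The submitters' processing notes name fastp 0.23.2, STAR 2.7.11, featureCounts and DESeq2 (the latter pair without a version) and the build mm10, also called GRCm38. The annotation, the strand setting of the counting and the treatment of reads that map to several genes are not given in the sources used here. The authors deposited a table of whole-number values per gene and library, described as raw counts, with 24000 rows and 6 columns, and these counts were used as deposited. Each column was assigned to its library by the group and replicate number in its name.

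Totals per library ran from 8353008 to 8916090, the median row held 18 counts in each library, and TMM factors lay between 0.972 and 1.035. None of the 15 pairs of libraries was identical. Rows were sorted by the form of their name into 1589 symbols, 20760 names made of Gm and a number, and 1651 names ending in Rik. Names and gene models were looked up in GENCODE M21, an annotation of GRCm38, and in tables of current symbols and synonyms. Of the symbols, 1116 were in GENCODE M21, 2 were other current symbols, 93 were older symbols or synonyms and 378 were unmatched. Of the Gm rows, 12177 (58.7%) were in GENCODE M21, 2782 were other current symbols, 1217 were older symbols or synonyms and 4584 (22.1%) were unmatched. Positions are 1-based on GRCm38 and were taken from GENCODE M21 by name.

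The test compared N-bc2S1P with saline over all 6 libraries with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filter filterByExpr, robust dispersion estimates and no covariate. It was two-sided, and a row passed at a Benjamini-Hochberg adjusted p under 0.05 over the 17099 rows tested. Fold changes are log2 ratios of N-bc2S1P over saline, and their standard errors are the log2 ratio divided by the square root of the F statistic. Levels are CPM, counts relative to the library total scaled by TMM, as mean ± SD of 3 libraries. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 46 lists, 10 had at least 5 tested members and were tested, 22 had 1 to 4 and 14 had no member in the table. The separation of the groups was measured as the mean distance between groups minus that within groups over the 1000 most variable rows, with an exact permutation test.

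Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per direction, the 10 symbols with the largest fold change among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups, then the 3 members with the smallest p in the direction of each list past the threshold, and 18 genes always to be named, none of which had a row in the table used here. The values of some genes that the rule takes are not reported here. Alternatives were DESeq2 1.42.0, other normalisation factors, other filters, limma-voom, the replicate number as a block and leaving out each library. A further 6 lists, families of symbols with a shared prefix, fits on symbols alone and on names in GENCODE M21, and the checks of spread, fold size, names and gene length were chosen after the values had been seen. These used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

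The steps were tested on simulated data. For N-bc2S1P against saline, counts were drawn for the 17099 rows tested, with a dispersion of 0.03 and 200 changed genes. After the filter was applied to the simulated counts, 16684 genes were fitted. The test recovered 51% of changes of 1 and 99% of changes of 2 on the log2 scale, with 6 false calls among 156. On the same simulated counts camera called 2 of 2 changed lists and 0 of 10 unchanged ones. The simulation gave all genes the same dispersion. In the deposited table, low Gm and Rik rows had a variance over mean of 0.21, and 1443 of 1589 symbols passed the threshold. The recovery and error rates above therefore do not carry over to it. Poisson counts drawn at the means of 9961 Gm and Rik rows gave a variance over mean of 1.005 by the measure used for replicate spread, and counts with added biological variance gave 1.388.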

Results

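CA1 tissue of P14 mice was profiled by sequencing of total RNA to compare animals given N-bc2S1P, a compound known here by its code name only, with animals given saline. Each group had 3 libraries, and the series gives 3 mice per group. Dose, route, timing and the sex of the mice are not given in the sources used here. Total counts were 8681704, 8713118 and 8916090 in the N-bc2S1P libraries and 8774309, 8353008 and 8447501 in the saline libraries. The table held 24000 rows, of which 1589 were named with a gene symbol, 20760 with a Gm number and 1651 with a Rik name.

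Several measured properties of the table bear on every value below. Among 9961 Gm and Rik rows with mean counts of 5 to 50, the variance between replicates was 0.21 ± 0.0016 (SE) times the mean, where Poisson counting error alone gave 1.005 in simulated counts. The symbols filled the first 1589 rows, and the 1552 listed before Actb had a median absolute log2 fold change of 1.90, with 95.8% of them between 1.5 and 2.1. None of the 1651 Rik names matched GENCODE M21, a current symbol or a synonym, and 473 symbols were not in GENCODE M21, among them Il8 and Cyp3a4. Of 12 abundant brain and mitochondrial genes looked up, including Mbp, Snap25, Camk2a, Gfap and mt-Co1, only Slc1a2 had a row in the table used here. The p-values below come from a model of independent read counts, which these values did not meet, so they describe the deposited table and do not measure the error of a sequencing experiment.

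In the deposited table, N-bc2S1P libraries held higher values than saline libraries for the Notch ligands Jag2 and Dll1, for Ncstn, which encodes the gamma-secretase subunit nicastrin, and for the transcriptional repressors Hey1, Hey2 and Hes3. They held lower values for the kinases Fgr and Tyk2, for Irs2, an adaptor of the insulin receptor, and for the homeobox gene Hoxa10. In lists fixed beforehand, 14 of 20 inflammatory genes with a row were higher. Of those with a row, 8 of 9 ionotropic glutamate receptor genes, 6 of 6 apoptosis genes and 3 of 5 heat shock genes were lower. The full lists held 25, 27, 19 and 15 genes, so the rest of each list was not measured. These lists passed camera at a preset correlation and not with an estimated correlation, where their adjusted p were 0.0517, 0.0577, 0.0517 and 0.0684, and no list passed when set against the other symbols alone. By the edgeR quasi-likelihood test 1450 of 17099 rows passed an adjusted p of 0.05, 805 higher and 645 lower with N-bc2S1P, and 1752 had an unadjusted p under 0.05. Symbols made up 1443 of these rows, 801 higher and 642 lower, at median folds of 3.76 higher and 3.75 lower. The libraries of the groups did not overlap in 95.3% of the tested symbols, against 10.8% of Gm rows and 11.2% of Rik rows, where chance gives 10%. Outside the symbols 5 Gm rows (Gm22097, Gm10828, Gm21724, Gm23736 and Gm24458) and 2 Rik rows (5772816C97Rik and 2314300K17Rik) passed, with log2 fold changes of at most 0.447 in size, and these names were picked after the values were seen. The mean distance between groups exceeded that within groups by 41.5 (61.8 against 20.3), and the exact one-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. All of the 1000 most variable rows used for this distance were symbols, so it does not describe the Gm and Rik rows.

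**Figure D1:**
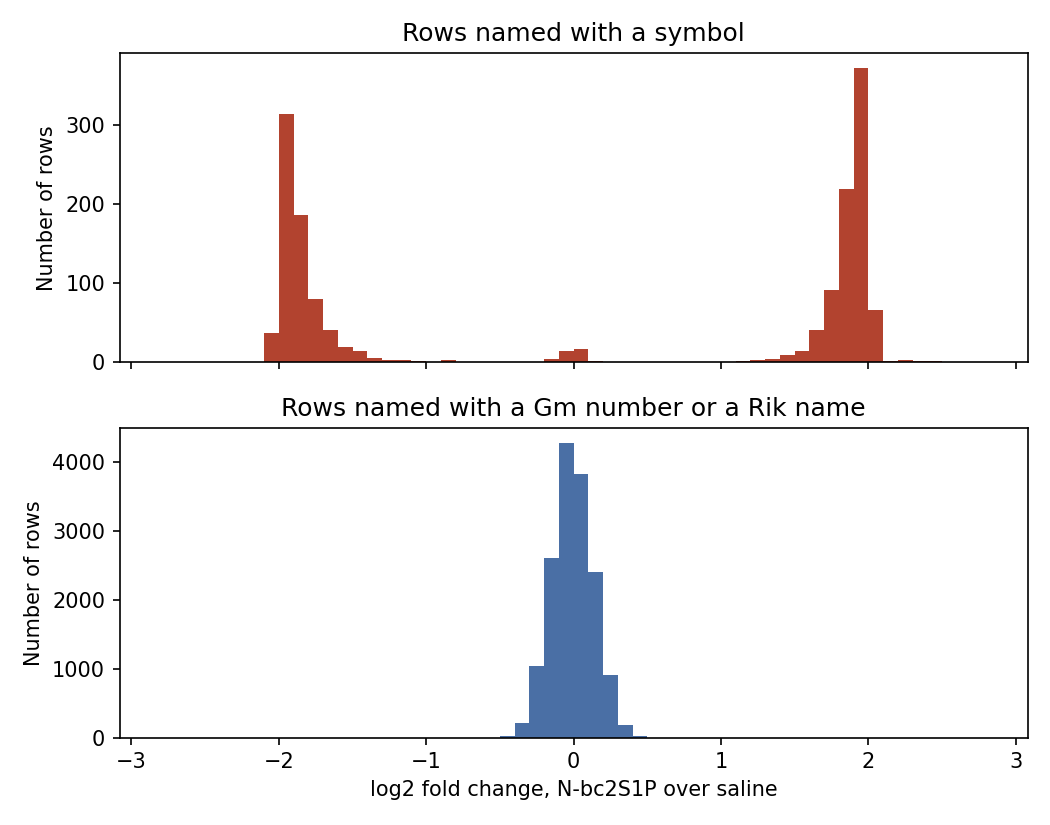
Histograms of the log2 fold change of N-bc2S1P over saline (horizontal axis) against the number of rows (vertical axis), for rows named with a symbol (top) and with a Gm number or Rik name (bottom). Symbols gathered in narrow peaks on both sides of 0, at medians of 1.91 and -1.91 among those past the threshold, and the other rows formed a peak at 0.

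Ncstn had the largest increase of the named genes. It went from 38.8 ± 10.9 CPM with saline to 230.1 ± 110.4 CPM with N-bc2S1P (mean ± SD, n = 3 each). Its log2 fold change was 2.57 ± 0.23 (SE, edgeR adjusted p = 2.42e-21). The adjusted p of Ncstn was 7.01e-06 with DESeq2 and 0.000115 by edgeR with symbols alone. The edgeR SE draws on the dispersions of all rows, so it does not measure the spread between the libraries of a gene alone. From the replicates alone, the median SE of the log2 ratio was 0.31 over the symbols before Actb. Jag2 went from 62.2 ± 36.1 to 347.9 ± 78.1 CPM, a log2 fold change of 2.48 ± 0.22 (edgeR adjusted p = 6.76e-18), which was 3.07 without saline replicate 3. Hey2 and Hey1 were higher by 2.35 ± 0.30 and 2.24 ± 0.48 on the log2 scale, and Hes3 and Dll1 by 2.19 ± 0.21 and 2.15 ± 0.31. The other increases were in Col6a5, which encodes a collagen VI chain, and Itgb5, an integrin subunit, both 4.17-fold, and in Znf602 and Znf280, at 4.17-fold and 4.15-fold, neither of which is a name in GENCODE M21. In these last 4 the replicates lay close together, as in Znf280 with 256.1 ± 24.0 against 61.7 ± 3.74 CPM, while the SD of Hey2 with N-bc2S1P was 218.1 CPM on a mean of 460.2. The calls for Ncstn, Hey2, Hey1 and Dll1 ended with limma-voom, at adjusted p of 0.13, 0.0994, 0.186 and 0.231, while over their other alternatives the adjusted p reached as low as 1.98e-30, 4.24e-35, 8.19e-27 and 6.72e-29 and as high as 0.0313, 0.478, 0.296 and 0.0826. The call for Hey2 also ended with the replicate number as a block, at a log2 fold change of 2.28 and an edgeR adjusted p of 0.478. That for Dll1 also ended with the strict filter, at a log2 fold change of 2.13 and an edgeR adjusted p of 0.0826. For Hey1 the edgeR adjusted p was 0.0443 with all libraries and 0.296 without saline replicate 3, at log2 fold changes of 2.24 and 2.27, and 0.0851 with all libraries and the strict filter.

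Fgr, a Src-family kinase, showed the largest decrease of the named genes, from 243.4 ± 29.2 CPM with saline to 57.7 ± 2.12 CPM with N-bc2S1P, which is 4.21-fold lower (log2 fold change -2.08 ± 0.21, edgeR adjusted p = 2.14e-21). Tyk2, a Janus kinase, fell from 362.9 ± 99.8 to 87.4 ± 6.22 CPM, 4.15-fold lower. Irs2 fell from 144.1 ± 36.5 to 34.8 ± 2.86 CPM, 4.14-fold lower. Hoxa10, the transporter gene Abcc10, the kinesin gene Kif7, the chemokine gene Ccl22 and Rhobtb1 had log2 fold changes of -2.04, -2.04, -2.03, -2.03 and -2.03. Gng9 and Kif25, names not in GENCODE M21, had log2 fold changes of -2.04 each. The 10 decreases thus spanned -2.08 to -2.03, and the smallest SE among them was 0.17 for Gng9. They were chosen as the largest among 642 lower symbols past the threshold. Their range therefore does not measure how alike the fold sizes of all symbols were, which is taken up below for the symbols before Actb.

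On GRCm38, Ncstn is a protein-coding gene on the minus strand of chromosome 1, from 172066013 to 172082795, and Jag2 lies on the minus strand of chromosome 12, from 112907819 to 112929776. Dll1 spans 15367354 to 15376872 on chromosome 17, Hey1 8663359 to 8667256 on chromosome 3 and Hey2 30832359 to 30842801 on chromosome 10, all on the minus strand. Fgr spans 132974095 to 133001910 on the plus strand of chromosome 4. Tyk2 lies on chromosome 9, from 21104068 to 21131243, and Irs2 on chromosome 8, from 10984681 to 11008458, both on the minus strand.

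**Figure D2:**
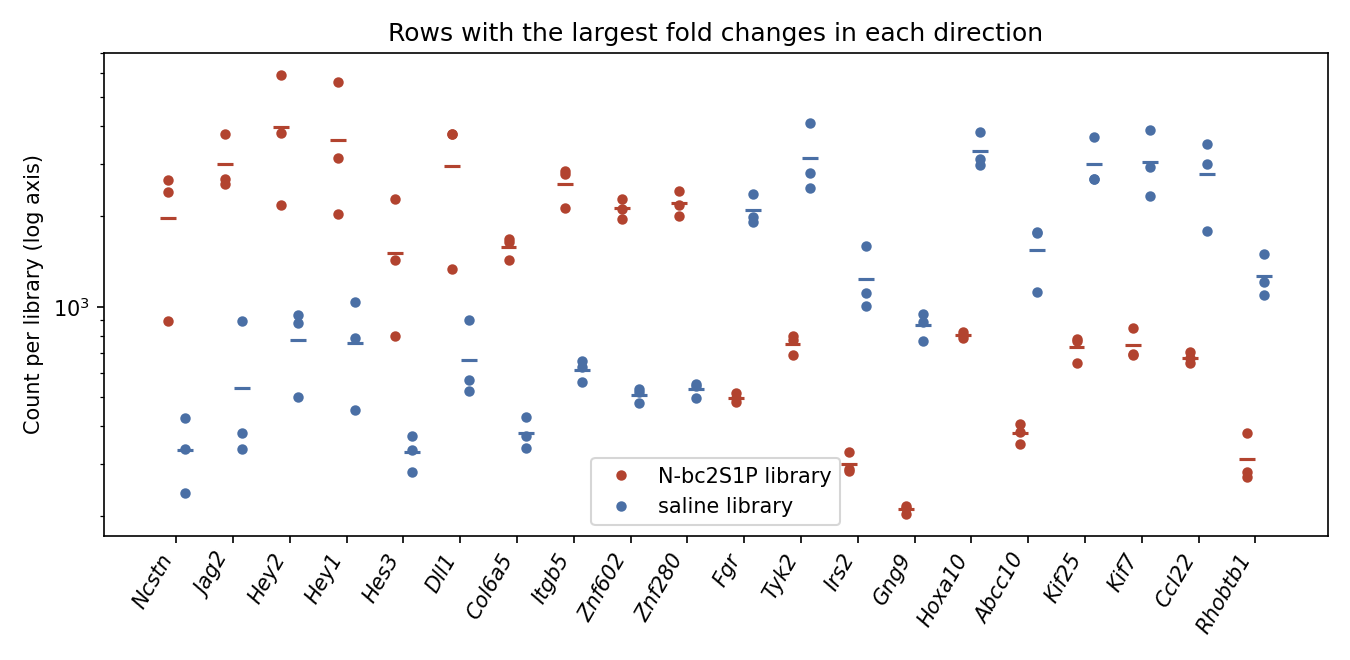
Counts per library (vertical log axis) of the 10 symbols with the largest increase and the 10 with the largest decrease, with N-bc2S1P libraries in red and saline libraries in blue. Points are libraries and bars are means of 3, and in all of these symbols the colours do not overlap.

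Among the lists of genes fixed beforehand, 5 of 10 tested passed camera at its preset correlation, and 6 had an unadjusted p under 0.05. For each list, the numbers of genes given here and below count only the members with a row. The full inflammatory, glutamate receptor, apoptosis, heat shock and hypoxia lists held 25, 27, 19, 15 and 22 genes. Of 20 inflammatory cytokine and NF-kB target genes, 14 were higher, 5 lower and 1 did not pass (median log2 fold change 1.83, camera adjusted p = 2.33e-08, adjusted p = 0.0517 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, was 3.94-fold higher at 464.2 ± 81.9 against 117.8 ± 30.6 CPM, Il1b was 3.89-fold higher and the chemokine gene Ccl4 3.53-fold. Ccl3, Ccl5, Cxcl1, Tnfaip3 and Tgfb1 were lower, at log2 fold changes of -1.80, -1.92, -1.94, -1.95 and -1.62. Tnfaip3 encodes an inhibitor of NF-kB signalling and Tgfb1 an anti-inflammatory cytokine, and Il10, another such cytokine, was higher by 1.68 on the log2 scale. The tested blood cell markers, Ptprc of leukocytes and Slc4a1 of erythrocytes, were both higher too, by 1.98 and 1.95 on the log2 scale.

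Of 9 genes for ionotropic glutamate receptors and their auxiliary subunits, 8 were lower and Grik1 was higher (median log2 fold change -1.88, camera adjusted p = 2.33e-08, adjusted p = 0.0577 with an estimated correlation). The AMPA receptor genes Gria3 and Gria4 had log2 fold changes of -1.98 ± 0.18 and -1.90 ± 0.19, and Cacng2, which encodes the AMPA receptor partner stargazin, -1.87 ± 0.20. Grin1, the obligatory NMDA receptor subunit, had a log2 fold change of -1.83. All 6 p53 target and apoptosis genes with a row, of 19 on the list, were lower (median -1.90, camera adjusted p = 9.66e-11, adjusted p = 0.0517 with an estimated correlation). They included the pro-apoptotic Bax and the caspase gene Casp9 as well as Bcl2, which acts against apoptosis. Bax fell from 326.1 ± 128.2 to 87.6 ± 2.98 CPM and Casp9 from 96.3 ± 8.75 to 25.6 ± 7.43 CPM.

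Of 5 heat shock genes, Hspa8, Hsp90ab1 and Hspa1a were lower, at log2 fold changes of -1.91, -1.91 and -1.88, and Hsph1 and Hspd1 did not pass, at 1.31 and -0.06 (camera adjusted p = 0.00217 for the list, adjusted p = 0.0684 with an estimated correlation). Hspa1a has a near-identical copy, Hspa1b, so its count is uncertain. Of 6 hypoxia and glycolysis genes, Ldha, Pkm and Vegfa were lower by 3.95, 3.90 and 3.80-fold, the glucose transporter gene Slc2a1 was higher by 1.81 on the log2 scale, and Pgk1 and Gapdh did not pass, at 0.09 and -0.04 (camera adjusted p = 0.0163 for the list, adjusted p = 0.237 with an estimated correlation). With an estimated correlation none of the 10 lists passed camera and 4 had an unadjusted p under 0.05. The heat shock list fell short although its estimated correlation, -0.105, was below the preset 0.01. A larger correlation between members thus does not account for the loss of that list. By contrast 6 lists passed fry, which asks whether the members of a list move to one side and does not compare them with other genes. When the lists were set against the other symbols alone, a comparison added after the values were seen, 0 passed camera, 2 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0829.

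The other 5 lists held members that moved both ways. Of 11 genes for GABA receptors and chloride transporters, 5 were higher, among them Gabra2 and Gabrg1, and 6 lower, among them Gabra4 and Gabra5 (camera adjusted p = 0.594). Of 17 voltage-gated channel genes 7 were higher, such as Cacna1g and Cacna1b, 5 lower, such as Kcna2 and Cacna1e, and 5 did not pass (camera adjusted p = 0.947). The median of that list was -1.45, the mean -0.08 and the direction in camera up. Of 24 nuclear-encoded oxidative phosphorylation genes 12 were higher and 8 lower (camera adjusted p = 0.0611), and the camera adjusted p of this list ran from 0.0267 with library size only to 0.878 with symbols alone over the alternatives and was 0.0499 without N-bc2S1P replicate 2. Of 44 cytosolic ribosomal protein genes, 16 were higher, 16 lower and 12 did not pass (camera adjusted p = 0.947). This list had a median of 0.01, a mean of -0.01 and the direction up in camera. Whether reads of processed pseudogenes entered its values was not tested. Rplp1 and Rplp0, partners in the same ribosomal stalk, had log2 fold changes of 2.04 and -1.90. Of 9 meningeal and fibroblast genes 4 were higher, such as Lum and Dcn, and 4 lower, the collagens Col1a1, Col1a2 and Col3a1 and the transporter gene Slc22a6 (camera adjusted p = 0.589). Adjusted over the list alone, the members past 0.05 were 19 of the inflammatory list, 9 glutamate receptor, 6 apoptosis, 3 heat shock, 4 hypoxia, 9 meningeal, 11 GABA, 12 channel, 20 oxidative phosphorylation and 32 ribosomal protein genes, against 19, 9, 6, 3, 4, 8, 11, 12, 20 and 32 over all rows tested.

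The 22 lists with 1 to 4 tested members were described without a test, and of their 43 genes 20 were higher, 20 lower and 3 did not pass. As examples, the neurotrophic factor and receptor genes Igf1, Igf1r, Fgf2 and Vegfa were all lower, the neurogenesis genes Sox2, Sox4 and Tubb3 were all higher, and of 4 astrocyte genes Slc1a3 was higher and Slc1a2, Sox9 and Fgfr3 lower. Of the 14 lists with no member in the table used here, several were chosen for the treatment or the tissue, among them S1P receptors and enzymes, sphingolipid synthesis, histone deacetylases, CA1 pyramidal neuron markers, microglia and myelin. The 37 symbols from Actb on, which included Gapdh, Rpl13a, Canx and Rps19, had a largest absolute log2 fold change of 0.167, a median of 0.051 and edgeR adjusted p of at least 0.997. Their median within-group coefficient of variation was 5.90%, against 26.3% for the symbols before Actb.

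**Figure D3:**
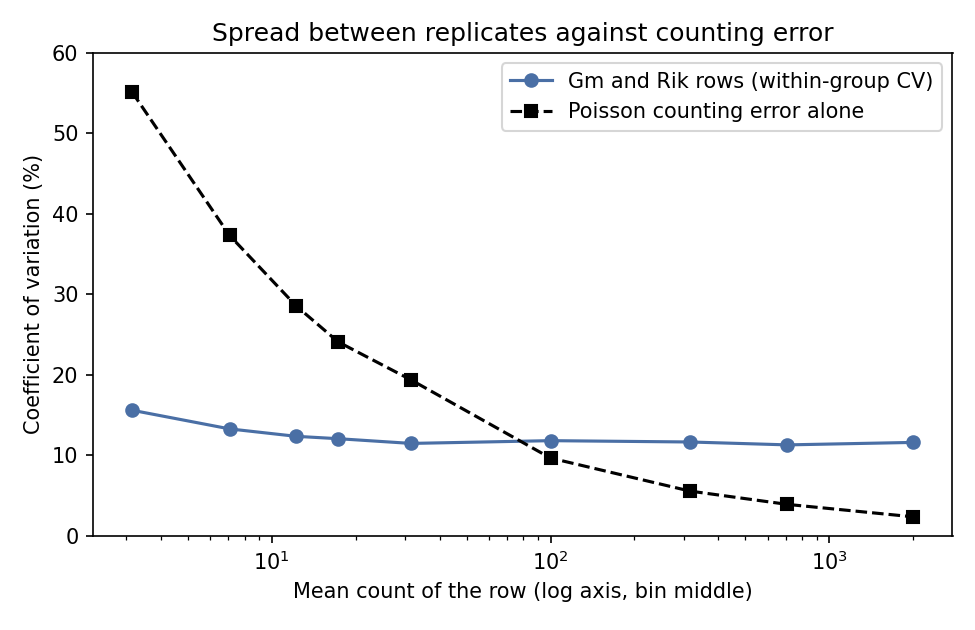
Coefficient of variation between replicates (percent, vertical axis) against the mean count of Gm and Rik rows (log axis), with the value that Poisson counting error alone gives as a dashed line. The measured variation stayed between 11.3% and 15.6% while the counting error fell from 55.1% to 2.34%, and the measured points lay below the dashed line for the bins below a mean count of 50.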

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

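The tests on symbols alone and on names in GENCODE M21 and the test of other splits were written down after the values were seen. The count of rows past the threshold, 1450, ranged from 1313 with the strict filter to 1525 with DESeq2, which left 9966 adjusted p as NA and shared 1442 of its calls with edgeR. It was 1015 with names in GENCODE M21 and 1577 with symbols alone, where the median log2 fold change of all rows was 1.25. Leaving out each library gave 1471 to 1494 rows and 5 to 6 lists. Higher and lower counts kept within 1.5 times the reported ones in each of these. With an estimated correlation 0 lists passed, and with symbols alone 0 passed, both with factors of their own and with the factors of all rows, where only the rows that the lists were set against differed. The strict filter left 4 lists, without the hypoxia list at an adjusted p of 0.0695 (0.0139 to 0.502 over the camera alternatives), against 5 reported. Of 556 values of the 35 named genes under alternatives, 548 kept their direction and side of the threshold, 8 fell short of it (Ncstn, Hey2, Hey1 and Dll1; the cause was not tested) and 0 reversed. The replicate numbers did not pair the libraries, as same-numbered libraries correlated at -0.036, 0.001 and -0.017 and 0 of 6 correlated best with their own number. With the replicate number as a block 1388 rows (768 higher, 620 lower) and 5 lists passed. The separation of the groups stayed at p = 0.1 by the exact permutation test in each setting. With 10 splits of the 6 libraries no share under 0.05 can arise; 1 of the 10, the real split, gave as many as 1450 rows and the highest other split gave 1. Sex as a covariate and removal of mitochondrial genes were not run, because no row of such genes was in the table used here. What depth limits could not be measured, since replicates of low rows varied less than counting error.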

Other observations

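All tests in this part were chosen after the values they concern had been seen. Genes of 6 signalling pathways were listed with the values in view, so their counts describe the deposited table and no test of them is given. Only listed genes with a row are counted. Of 35 genes of the Notch pathway, 28 were higher with N-bc2S1P, 0 lower and 7 did not pass by edgeR, against 801 higher and 642 lower among all symbols past the threshold. Receptor genes were among them, with log2 fold changes of 1.94 for Notch1, 1.88 for Notch2 and 0.93 for Notch4. Of 24 genes of insulin, PI3K, AKT, mTOR and AMPK signalling, 22 were lower and 0 higher, and activators such as Pdpk1 and Mtor fell together with the inhibitors Tsc1 and Tsc2. Of 23 genes of the RAS and MAP kinase cascade 20 were lower and 1 higher, and of 21 genes of cell death receptors, caspases and the BCL2 family 17 were lower and 2, Casp1 and Casp6, higher. Among 16 genes of WNT signalling 6 were higher and 8 lower, and among 18 genes of Toll-like receptors and interferon induction 12 were higher and 6 lower.

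Of 24 families that share only a prefix of the symbol and have at least 10 symbols past the threshold, 2 differed in direction from the other symbols by Fisher's exact test (two-sided, adjusted over the families). In these, 28 of 30 Cd symbols past the threshold (adjusted p = 0.000172) and 17 of 17 such Gpr symbols (adjusted p = 0.000756) were higher. These tests treat symbols as independent. All 10 symbols before Actb with a log2 fold change above 2.1 were in the Notch list, which was compiled with the values in view. Among these symbols Jag1, Dll4, Hes1 and Mfng did not pass, at edgeR adjusted p of 0.1065, 0.2205, 0.1628 and 0.1977. The median within-group coefficient of variation of the Notch list was 40.0%, against 26.2% for the other symbols before Actb.

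The fold sizes of the symbols were more alike than their replicates. A response measured in 3 independent libraries per group would leave about 50% of the 1552 symbols before Actb, or fewer, within 0.741 standard errors of the common fold (49.7% on average and 52.5% at most in 100 simulated draws), and 92.2% were (exact 95% interval 90.8% to 93.5%). Scaling between libraries moves all rows of a library to the same side, and 44.5% of the symbols past the threshold were lower and the rest higher. Values set to a common fold or adjusted after counting may be the source, since single pairs of libraries scattered 4.65 times as widely as the means of 3, where averaging independent pairs gives about 1.73 and the highest of 100 simulated draws was 1.86. These tests concern the spread of the values and do not show that N-bc2S1P had no effect on CA1.

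The replicate spread of the Gm and Rik rows was smaller than counting allows. Independent read counts have a variance over mean of at least 1, and 9961 rows, 41.5% of the table, had 0.21, with 50.7% of them under the 5th percentile of Poisson counts, where 5% belong. Fitted as a counting part plus a part that grows with the mean, and with rounding taken off, the ratio had a counting part of 0.024 (95% bootstrap interval 0.0181 to 0.03) and a relative spread of 11.5%. In simulated data the counting part was 0.0193 (0.0125 to 0.0251) for counts 50 times as deep, scaled down by a common factor, and -0.0011 (-0.0064 to 0.0051) for rounded values with the same relative spread in each row, so the measured one goes against that simplest form of made or edited values. Scaled deeper counts and values with a spread slightly wider in low rows, which has the same form as a counting part, may each lie behind this and cannot be told apart, and no biological explanation was tested.

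The names of the rows also departed from a mouse annotation in several ways. Older symbols of another annotation would be found in GENCODE M21, among current symbols or as synonyms, and 0% of the Rik names were, against 77.9% of the Gm numbers and 76.2% of the symbols. Yet 19520 of the 25000 Gm numbers in the range listed, 10000 to 34999, are names of a gene or synonyms. These were listed no more often than numbers in that range that were not found (82.9% against 83.7%, ratio 0.991, 95% interval 0.978 to 1.004), whereas symbols of a mouse annotation would favour the former. Of the Rik names, 83.0% ended in digits above 24, the highest in GENCODE M21. Of 305 symbols made of Znf and a number, 0 were in GENCODE M21 and 47 were older symbols or synonyms. A further 8 symbols started with Hla-. Assignment of reads to named genes by mapping would give longer gene models more counts, and across 11809 Gm rows, which are not independent replicates, the Spearman rho of mean count and exonic length was -0.012 (95% interval -0.03 to 0.006). Labels attached to values made in another way could give these results, how that came about stays open, and no biological explanation was tested.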
